A study of Mus musculus with 20 samples.

How the data were processed

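RNA from mouse brain monocytes and microglia, collected 3 days after permanent photothrombosis, was sequenced in 20 libraries, given in 2 tables. Photothrombosis is a stroke model in which a light-activated dye clots cortical vessels. The GFP table holds 8 libraries from Cxcr4-GFP reporter mice, with 4 of GFP-negative microglia and 4 of GFP-positive monocytes, so that population and reporter signal coincide. Each animal or pool gave 1 library of each population; 1 pair came from 2 mice, 1 from a pool of 5 mice and 2 from single mice. The Cre table holds 12 libraries of the Cxcr4CreER line, in which a Cre recombinase is active after tamoxifen, with 3 each of microglia and monocytes from control and from conditional knockout (KO) mice. Of these, 2 control and 2 KO animals gave libraries of both populations. In both genotypes the microglia are labelled TdT-negative and the monocytes TdT-positive, so that population and TdT signal coincide. KO microglia are thus TdT-negative cells of KO animals, and whether Cxcr4 was deleted in them is not shown. The labels give no other sort marker, no tamoxifen schedule and no sex, and gene-level values do not show which part of Cxcr4 was deleted. Titles of all GFP libraries carry the tag BrKo, as do those of the KO libraries of the Cre table, whose controls carry BrC. The labels do not explain this tag, so its meaning for the genotype of the GFP mice is not known here.

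The GFP libraries were made from total RNA with the Nugen Ovation SoLo kit and the Cre libraries from polyA RNA with SMART-Seq2. The authors name CASAVA 1.82 and DESeq2 for the GFP table, and bcl2fastq 2.20, kallisto and DESeq2 for the Cre table. The aligner of the GFP table, the genome build and the annotation are not given in the sources used here, so no coordinates are given. The deposited values are a signal in normalized counts: reads per gene divided by 1 size factor per library, as made by the authors with DESeq2. In both tables, 100% of the values above 0 lay within 0.01 of a whole multiple of the library's smallest value, and whole reads were recovered from this. The GFP table lists 16536 genes, of which 790 are at 0 in every library, and the Cre table lists 16140 genes, none with fewer than 10 reads over its libraries. In the Cre table, 656 names with altered hyphens or leading digits were restored, and 24 names had turned into dates and were kept in that form. The tables were normalized separately, and no level is compared between them.

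Reads per library ranged from 0.617 to 14.9 M in the GFP table, where the ribosomal transcript Rn45s took 22.1% to 48.3%, and from 9.73 to 56.8 M in the Cre table. A single read equals 0.104 to 2.58 normalized counts in the GFP libraries and 0.375 to 2.19 in the Cre libraries. Where every library of a group was at 0, the fold is given as a lower bound against a floor of 3 reads over the group. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules.

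Genes entered the tests with a value of 10 or more in at least 4 libraries (GFP) or 3 libraries (Cre), which left 7706 and 12432 genes. Values were compared as log2(value + 1) with limma 3.58.1 (moderated test with an intensity trend, two-sided) under R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called. The GFP table was fitted with 2 groups and the Cre table with 4 groups that shared 1 estimate of the spread. The genotype-by-population term tested whether the KO difference of monocytes differed from that of microglia. Cxcr4 was also compared by two-sided exact permutation tests, whose smallest p is 0.029 for 4 against 4 libraries and 0.1 for 3 against 3. These tests, and the shares of genes without overlap by chance, take all libraries as unpaired. Fold changes were correlated across genes, which are not independent replicates, so those correlations have no p.

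The comparisons, the tests, 29 gene lists of cell types and programmes and the rule for named genes were fixed before the data were examined. Lists with at least 4 tested members were compared with all other genes by camera from limma with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. Named genes were Cxcr4 and, per comparison, the 10 higher and 10 lower called genes with the largest log2 fold, a mean of 50 or more in a group and no overlap between groups. Predicted genes, pseudogenes and antigen receptor segments were left out. Per list, up to 4 called members were taken, or the 2 with the smallest p where none was called, and the 10 smallest p where fewer than 5 genes were called. The text goes down each ranking; some genes of the rankings are not reported here. Prtn3, Ctsg and Mpo in KO against control monocytes were chosen after their values were seen.

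Alternatives were a pseudocount of 10, no filter, a filter of 50, upper quartile scaling, CPM scaling (to equal library totals), array weights, robust variance, the animal as a block and only the compared groups in the fit. Further ones were a fold of 2 or more, edgeR 4.0.16 (quasi-likelihood, recovered reads) and leaving out each library in turn. DESeq2 1.42.0 on recovered reads, the GFP fit without the libraries under 6000 detected genes, and sex read from sex-linked genes as a covariate were added after seeing the data. The fit was tested on simulated data, drawn with the spread estimated from each table, in which 50 genes per step were raised in 1 group. The raised genes were drawn from those with a mean of 50 or more, and every other gene had the same mean in all libraries. With limma, 46% of the GFP genes, 38% of the monocyte genes and 42% of the microglia genes changed by a factor of 16 were called, and 20%, 26% and 30% of those changed by a factor of 8. At factors of 2 and 4, 0% to 12% were called, and false calls numbered 0 to 2. No gene was set to be absent from a whole group, so these rates do not cover calls of such genes. The libraries of each group were checked for duplicates; the closest pair differed 6.3 times more than counting noise (chi-square per degree of freedom). No library was left out of the comparisons. Tables were prepared with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.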

Results

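RNA was measured in monocytes and microglia of mouse brains 3 days after a photothrombotic stroke. The 4 GFP microglia libraries held 0.617, 5.55, 1.11 and 0.851 M reads, and the 4 GFP monocyte libraries held 2.45, 14.9, 0.883 and 0.648 M. In the Cre table, control microglia had 27.2, 15.9 and 23.8 M reads, control monocytes 26.2, 10.4 and 14.5 M, KO microglia 17.7, 9.73 and 20.85 M, and KO monocytes 23.7, 56.8 and 30.6 M. GFP microglia 3, GFP microglia 4 and GFP monocytes 3 had 5598, 3489 and 3029 detected genes, against 10422 to 14498 in the other 5 GFP libraries. Cre libraries had 10350 to 13316 detected genes. Values are normalized counts with SD and log2 fold changes with SE, with n = 4 per GFP group and n = 3 per Cre group. Each gene called different was apart in all libraries of both groups where it is named below.

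The first question was which genes set Cxcr4-expressing monocytes apart from the microglia of the same brains. In Cxcr4-GFP mice, monocytes carried Cxcr4, the receptor of the chemokine Cxcl12, at 2277 ± 794 normalized counts against 4.84 ± 5.62 in microglia. The populations are labelled by the Cxcr4-GFP signal itself, so this difference is a check of the labels. The MHC class II genes H2-Aa, H2-Ab1 and Cd74, which present antigen to CD4 T cells, were higher in monocytes, and so were the monocyte antigen Ly6c2, the matrix protein Thbs1 and the lipid carrier Apoe. Microglia were higher in Sall1, a transcription factor of microglial identity, in Siglech and Slc2a5, and in the C1q chains of complement. Limma called 70 of 7706 genes, 32 higher and 38 lower in monocytes, and 580 genes had an unadjusted p under 0.05.

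The log2 fold of Cxcr4 was 9.37 (SE 1.30, adjusted p 7.69e-05, and exact permutation p 0.029, the smallest that 4 against 4 unpaired libraries allow). Only 8 splits part all 4 pairs from 1 animal or pool, too few for a permutation p under 0.05. H2-Aa had the largest fitted rise among the named genes, at 2218 ± 399 in monocytes against 1.72 ± 2.44 (log2 10.08, SE 1.34, adjusted p 4.44e-05). Ly6c2 was at 1076 ± 1395 in monocytes and at 0 in all 4 microglia libraries, at least 1501-fold higher (adjusted p 0.00845), or at least 538-fold without GFP monocytes 3. Emp1, a membrane protein, was at 807 ± 269 against 0.108 ± 0.215 (adjusted p 0.00246), Myof at 399 ± 165 against 0.215 ± 0.43 (adjusted p 0.0193) and Slfn4 at 465 ± 208 against 0.624 ± 1.25 (adjusted p 0.016), each with 1 or 2 reads in microglia. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by a log2 fold of 9.09 (SE 1.24), Cd74 by 8.86 (SE 0.99), H2-Ab1 by 8.26 (SE 1.40) and Thbs1 by 8.25 (adjusted p 1.57e-05). Among lower genes, the matrix protein Npnt was at 0.209 ± 0.295 in monocytes, with 3 reads, against 343 ± 145 (adjusted p 0.0263). Egr3, a transcription factor of the immediate early class, had a log2 fold of -7.13 (SE 1.57). Sall1 stood at 22.2 ± 20.1 against 1451 ± 469 (log2 -6.87, SE 1.19), and the fructose transporter Slc2a5 at 5.28 ± 6.81 against 429 ± 178 (log2 -6.84, adjusted p 0.038). The tight junction gene Tjp1 (-6.75), Adgrg1 (-6.62), Sall3 (-6.48), the calcium channel gene Cacna1a (-6.46), Nav3 (-6.39) and the microglial lectin Siglech (-6.34) completed the 10 largest falls.

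The homeostatic microglia list fell: of 25 tested genes 15 fell and 10 did not pass the test (21 fell adjusted over the list alone), with a median log2 fold of -4.49 and a camera adjusted p of 4.26e-55 (adjusted p = 0.0328 with an estimated correlation). It includes the fractalkine receptor Cx3cr1 (log2 -2.45, SE 0.43). In the monocyte list 8 of 22 genes rose (22 adjusted over the list alone), with a median of 6.14, or 6.24 with Ly6c2 at its bound (adjusted p 3.48e-36; adjusted p = 0.0248 with an estimated correlation). Tgfbi, a matrix protein, rose by 7.73 (SE 1.20) and the lectin Lgals3 by 6.99 (SE 1.67). Of 7 MHC class II genes 3 rose (4 adjusted over the list alone), with a median of 4.89 (adjusted p 7.95e-10; adjusted p = 0.0641 with an estimated correlation). In the MHC class I list B2m alone among 12 genes rose (1 adjusted over the list alone), by 1.12 (SE 0.26), and the median was 1.19 (adjusted p 0.0319; adjusted p = 0.145 with an estimated correlation). In the alternative activation list Gpnmb, Thbs1 and Spp1 (4.28, SE 0.96) rose among 13 genes (6 adjusted over the list alone; median 3.96, adjusted p 1.29e-07; adjusted p = 0.145 with an estimated correlation).

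In the disease-associated microglia list 5 of 21 genes rose (8 rose and 2 fell adjusted over the list alone), with a median of 1.46 (adjusted p 0.000281; adjusted p = 0.223 with an estimated correlation). Apoe stood at 12222 ± 4162 against 823 ± 762 (log2 4.52, SE 0.53, adjusted p 1.13e-05), and the inhibitory receptor Lilrb4a rose by 4.95 (SE 1.19). In the adhesion list the integrin Itga4 (6.54, SE 1.51) and the hyaluronan receptor Cd44 (5.85, SE 1.22) rose among 11 genes (5 rose and 1 fell adjusted over the list alone; median 3.16, adjusted p 0.0319; adjusted p = 0.253 with an estimated correlation). In the chemokine receptor list Cxcr4 rose and Cx3cr1 fell among 9 genes (4 rose and 1 fell adjusted over the list alone; median 2.63, adjusted p 0.0319; adjusted p = 0.253 with an estimated correlation). Because the populations are labelled by the Cxcr4-GFP signal, the rise of Cxcr4 in this list is again a check of the labels. The list was not tested without Cxcr4. The immediate early list fell, with Egr1 (log2 -3.90, SE 0.52) and Jun (log2 -2.09, SE 0.42) called among 18 genes (3 adjusted over the list alone; median -0.73, adjusted p 2.55e-09; adjusted p = 0.0901 with an estimated correlation). Without a called gene, the lists of interferon response (18 genes, 0 adjusted over the list alone, median 1.56, adjusted p 0.00838), glycolysis and hypoxia (20 genes, 0 adjusted over the list alone, median 1.96, adjusted p 0.00194) and border-associated macrophages (5 genes, 2 adjusted over the list alone, median 2.68, adjusted p 0.00838) were higher. These calls were lost with an estimated correlation, with adjusted p = 0.366, 0.253 and 0.203. Ms4a7, a marker of border-associated and monocyte-derived macrophages, had a log2 fold of 6.63 (SE 1.78, adjusted p 0.0768).

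Camera did not call the other 7 tested lists. Their adjusted p was 0.682 for inflammatory cytokines (Il1a fell, log2 -5.44, SE 1.18; 5 rose and 4 fell adjusted over the list alone), 0.188 for cell cycle (0 adjusted over the list alone) and 0.336 for cholesterol (1 adjusted over the list alone). It was 0.285 for complement (5 rose and 5 fell adjusted over the list alone), in which Cd93 rose (7.95, SE 1.94) and C1qa (-2.79, SE 0.65), C1qc (-2.31, SE 0.48) and C1qb (-2.05, SE 0.47) fell. It was 0.57 for lysosome (Psap rose by 1.08, SE 0.20; 1 rose and 3 fell adjusted over the list alone), 0.339 for myeloid transcription factors (2 rose and 2 fell adjusted over the list alone) and 0.0917 for sex-linked genes (1 fell adjusted over the list alone). Signs differed in 4 lists: cell cycle (median 0.21, mean -0.47, camera down), complement (median -0.46, mean 0.96, camera down), lysosome (median 0.45, mean 0.12, camera down) and myeloid transcription factors (median 0.06, mean -0.02, camera down). The other 10 lists had fewer than 4 tested genes, among them B cell and erythroid with 0 and neutrophil with 2; in the dendritic cell list the actin bundler Fscn1 fell (log2 -6.04, SE 1.47).

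Groups did not overlap for 725 genes, 9.4% against 2.9% by chance. The count of 70 was 60 with the animal or pool as a block (52 shared), 33 without GFP microglia 3 and 129 without GFP monocytes 3. It was 1198 without the 3 libraries of few detected genes and 17 with upper quartile scaling. The balance of 32 higher and 38 lower genes depends on the setting. It turned to 13 and 4 with upper quartile scaling, 61 and 45 with CPM scaling, 113 and 74 with DESeq2 and 52 and 48 with edgeR. It was 58 and 39, 49 and 32, 20 and 13, and 38 and 18 without GFP microglia 1, 2, 3 and 4, and 69 and 60 without GFP monocytes 3. Without GFP monocytes 1, 2 and 4 it was 22 and 61, 21 and 56, and 21 and 62. The median log2 fold of all genes, 0.508, was 0.566 with upper quartile scaling, 0.65 with CPM scaling and -0.068 without the 3 libraries of few detected genes. It was 1.02, 1.05, 0.271 and -0.097 without GFP microglia 1, 2, 3 and 4, and 0.181, 0.244, 1.44 and 0.23 without GFP monocytes 1, 2, 3 and 4.

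**Figure D1:**
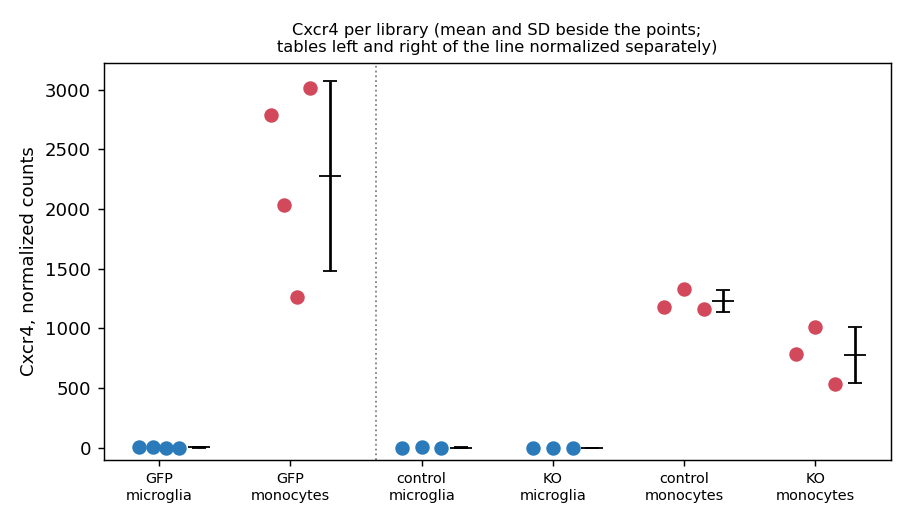
Cxcr4 in normalized counts (y axis) in each library (points) by group (x axis), with the mean and SD beside the points. Monocyte groups had means of 2277 (GFP), 1227 (control) and 777 (KO), and the means of the microglia groups were 4.84 or less; the GFP and Cre tables were normalized separately.

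The second question was how monocytes differ from microglia in control animals of the Cxcr4CreER line, measured with another kit. Control monocytes carried the chemokine receptor Ccr2 at 14015 ± 900.5 normalized counts against 14.1 ± 8.26 in microglia, and Cxcr4 at 1227 ± 91.4 against 2.63 ± 4.55. In both genotypes population and TdT signal coincide in a line named for Cxcr4, so higher Cxcr4 in monocytes may follow from the sort. Genes of the monocyte, neutrophil and MHC class II lists rose in monocytes, together with Anxa1, Clec4e and S100a9. The labels name no gate against neutrophils, so whether the neutrophil genes come from monocytes is not known here. In GFP mice the 2 tested genes of the neutrophil list had negative folds and were not called. The homeostatic microglia genes Sall1, Slc2a5 and Slco2b1 and the cell cycle genes Top2a and Cenpf were higher in microglia. Limma called 810 of 12432 genes, 430 higher and 380 lower in monocytes, and 2426 genes had an unadjusted p under 0.05.

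The log2 fold of Cxcr4 was 9.21 (SE 1.10, adjusted p 0.000431; exact permutation p 0.1, the smallest that 3 against 3 libraries allow). Anxa1, an annexin that restrains inflammation, stood at 11913 ± 1919 against 1.36 ± 1.18 (log2 12.46, SE 1.33, adjusted p 0.000213), and the lectin receptor Clec4e at 32535 ± 10579 against 47.4 ± 81.4 (log2 12.25, SE 1.48). Cd24a, Mgst1 and Ecm1 were at 0 in all 3 microglia libraries and at least 4659-fold, 4492-fold and 2633-fold higher in monocytes (adjusted p 8.12e-06, 0.000454 and 0.000454). With 1 read in microglia, Plbd1 was at 3419 ± 1062 against 0.234 ± 0.406 (adjusted p 0.000119) and Slamf7 at 3388 ± 1298 against 0.234 ± 0.406 (adjusted p 0.000926). Gpnmb rose by 11.26 (SE 0.97), Slfn4 by 11.10 (SE 1.35) and the calcium-binding alarmin S100a9 by 10.96 (SE 1.84). Ecscr, Tppp, Hspb3, Npnt and Gpr155 were at 0 in all 3 monocyte libraries and at least 1104-fold, 605-fold, 552-fold, 521-fold and 392-fold lower than in microglia (adjusted p 0.00233 to 0.0154). With 1 or 2 reads in monocytes, Gal3st4 was at 0.852 ± 1.48 against 1077 ± 629 (adjusted p 0.000463), Capn3 at 0.852 ± 1.48 against 997 ± 541 (adjusted p 0.000694) and Cenpe at 0.731 ± 1.27 against 718 ± 394 (adjusted p 0.00848). The protease Adamts1 (log2 -9.18, SE 2.00) and Golm1 (log2 -9.02, adjusted p 0.0113) also fell.

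All 28 homeostatic microglia genes were tested; 24 fell and 4 did not pass (27 fell adjusted over the list alone), with a median of -3.71 (adjusted p 2.96e-28; adjusted p = 0.0005 with an estimated correlation). Slc2a5 had a log2 fold of -8.54 (SE 1.98), the transporter Slco2b1 -7.53 (SE 1.39) and Sall1 -7.17 (SE 1.54). In the monocyte list 29 of 32 genes rose (32 adjusted over the list alone; median 5.93, adjusted p 6.99e-45; adjusted p = 6.03e-06 with an estimated correlation). Ly6c2 rose by 10.21 (SE 1.69), and haptoglobin, Hp, was at least 2120-fold higher. In the neutrophil list 7 of 16 genes rose (8 adjusted over the list alone), with a median of 6.18, or 7.35 with genes absent from microglia at their bound (adjusted p 1.54e-09; adjusted p = 0.0272 with an estimated correlation). Trem1, Retnlg and the collagenase Mmp8 were at 0 in microglia and at least 2289-fold, 1490-fold and 568-fold higher (Mmp8 at least 378-fold without control monocytes 2), and S100a8 rose by 9.10 (SE 2.28). In the border-associated macrophage list 3 of 11 genes rose (3 adjusted over the list alone; median 1.14, adjusted p 0.00564; adjusted p = 0.0434 with an estimated correlation), led by Ms4a7 at 40151 ± 2047 against 559 ± 296 (log2 6.34, SE 0.42). In the MHC class II list 4 of 10 rose (4 adjusted over the list alone; median 2.49, or 3.28 with bounds; adjusted p 1.16e-05; adjusted p = 0.0262 with an estimated correlation), with H2-Eb1 at 9.04 (SE 1.38), H2-Ab1 at 7.58 (SE 0.64) and Cd74 at 5.68 (SE 0.33).

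In the chemokine receptor list 4 of 14 genes rose and Cx3cr1 fell (7 rose and 1 fell adjusted over the list alone; median 1.68, or 3.16 with bounds; adjusted p 7.98e-06; adjusted p = 0.00607 with an estimated correlation). Ccr2 rose by 10.03 (SE 0.49) and Ccr1 by 5.15 (SE 0.82). Cxcr4, whose rise may follow from the sort, is also among the called genes of this list, which was not tested without it. In the alternative activation list 10 of 17 rose (10 rose and 2 fell adjusted over the list alone; median 3.68, adjusted p 6.22e-08; adjusted p = 0.00607 with an estimated correlation), with the vascular growth factor Vegfa at least 1704-fold higher. In the adhesion list 8 of 20 rose and 2 fell (10 rose and 4 fell adjusted over the list alone; median 2.84, adjusted p 5.59e-05; adjusted p = 0.0447 with an estimated correlation). The glycolysis and hypoxia list rose, 8 of 21 higher and 1 lower (13 rose and 2 fell adjusted over the list alone; median 1.21, adjusted p 2.28e-07; adjusted p = 0.00607 with an estimated correlation). In it Ndrg1 rose by 6.87 (SE 1.22) and the hexokinase Hk1 by 4.70 (SE 1.14), and the pyruvate dehydrogenase kinase Pdk1 fell (log2 -3.66, SE 0.82). The cell cycle list fell, 4 of 26 lower (11 adjusted over the list alone; median -3.24, adjusted p 8.65e-07; adjusted p = 0.00379 with an estimated correlation). The topoisomerase Top2a had a log2 fold of -3.04 (SE 0.61) and Cenpf -2.47 (SE 0.54).

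Calls of 4 further lists were lost with an estimated correlation. In the inflammatory list 10 of 20 genes rose and 3 fell (12 rose and 4 fell adjusted over the list alone; median 1.90, adjusted p 1.74e-05; adjusted p = 0.193 with an estimated correlation), with the chemokine Cxcl1 at 9.41 (SE 2.02), Il1rn at 6.31 (SE 0.49) and the prostaglandin synthase Ptgs2 at 4.51 (SE 0.54). In the interferon list 3 of 21 rose (8 adjusted over the list alone; median 1.22, adjusted p 4.08e-08; adjusted p = 0.236 with an estimated correlation), with Irf7 at 2.84 (SE 0.50) and the antiviral gene Rsad2 at 2.50 (SE 0.52). In the MHC class I list 2 of 13 rose (4 adjusted over the list alone; median 0.73, adjusted p 0.000517; adjusted p = 0.183 with an estimated correlation). In the disease-associated microglia list 8 of 21 rose and 4 fell (10 rose and 6 fell adjusted over the list alone; median 0.96, adjusted p 0.00385; adjusted p = 0.288 with an estimated correlation), with Apoe at 3.98 (SE 0.41).

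Camera did not call the other 14 tested lists, whose adjusted p ranged from 0.0925 (dendritic cell) to 0.808 (hematopoietic progenitor, neuron and oligodendrocyte lineage). Called members in them were Cd209a (8.83, SE 1.75) and Dpp4 (at least 539-fold, or 303-fold without control monocytes 3) among dendritic cell genes, Klrd1 (at least 255-fold) and Ccl5 (2.72, SE 0.71) among T and NK cell genes, and Cd34 (log2 -3.37, SE 0.90) among progenitor genes. Aldh1l1, an astrocyte enzyme, was at least 159-fold lower in monocytes and Slc1a3 had a log2 fold of -4.36 (SE 0.85). In complement, Cd93 rose by 8.31 (SE 0.93) and C1qc (-1.79, SE 0.29) and C1qa (-1.78, SE 0.34) were among 5 that fell. In the lysosome list Ctsl (-2.09, SE 0.19) was among 2 genes that fell, and 3 rose. Among myeloid transcription factors Runx3 rose by 10.11 (SE 1.07) and Sall3 fell (log2 -5.92, SE 0.65); immediate early genes had 2 higher, 3 lower, among them Jun (-2.89, SE 0.51), and cholesterol genes 1 higher and 1 lower. No B cell, neuron, oligodendrocyte, endothelial or sex-linked gene was called. Adjusted over the list alone, these 14 lists had 0 to 5 genes higher and 0 to 5 lower. Signs differed for complement (median -0.59, mean 1.12, camera down) and myeloid transcription factors (median -0.02, mean 0.20, camera up). The erythroid list had 3 tested genes.

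Groups did not overlap for 2751 genes, 22.1% against 10% by chance, and mitochondrial transcripts took 9.22% to 19% of reads in the microglia libraries of the Cre table and 2.7% to 4.86% in its monocyte libraries. The count of 810 was 478 with edgeR, 1614 with DESeq2 and 386 with only these groups in the fit. The majority of 430 higher against 380 lower genes turned to 338 against 452 with upper quartile scaling, 363 against 432 with CPM scaling, 752 against 862 with DESeq2 and 298 against 319 without control monocytes 1. The median log2 fold of all genes, -0.24, moved to -0.466 with upper quartile scaling and to -0.397 with CPM scaling, and the lysosome median of 0.01 then turned to -0.24 and -0.17.

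Across the 7343 genes tested in both tables, the log2 folds of GFP mice and of control mice had a Pearson r of 0.453 and a Spearman rho of 0.339. Of 69 genes called in GFP mice and tested here, 69 had the same sign, and 29 were called higher and 32 lower in both, against 1.29 and 1.17 by chance. Cxcr4, Gpnmb, Ly6c2 and Cd74 were higher and Npnt and Sall1 lower in both. This r was 0.602 without the 3 GFP libraries of few detected genes.

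**Figure D2:**
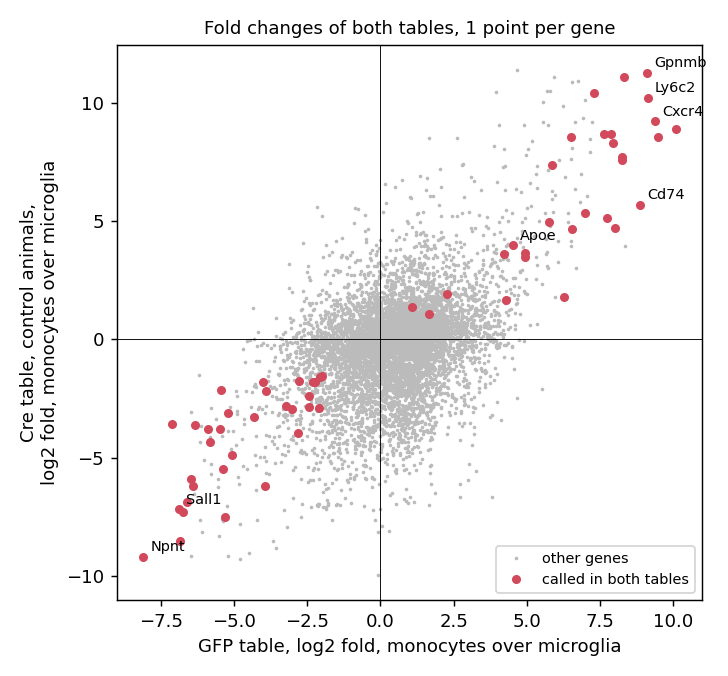
Log2 fold of monocytes over microglia in GFP mice (x axis) against control mice of the Cre table (y axis), with 1 point per gene. The 61 genes called in both tables (red) have the same sign in both, with Npnt at -8.09 and -9.19 and Cxcr4 at 9.37 and 9.21.

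The third question was how monocytes differ from microglia in KO animals. KO monocytes carried Ly6c2 at 20842 ± 10170 normalized counts, with 0 in all 3 KO microglia libraries, and Cxcr4 at 777 ± 237 against 0.304 ± 0.526. The monocyte, neutrophil, MHC class II and chemokine receptor lists rose, and the homeostatic microglia and cell cycle lists fell. As in control animals, whether the neutrophil genes come from monocytes is not known. The granule proteases Elane, Prtn3 and Ctsg, made by myeloid progenitors, were at 0 in KO microglia and rose in KO monocytes. Limma called 849 of 12432 genes, 479 higher and 370 lower in monocytes, and 2404 genes had an unadjusted p under 0.05.

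Cxcr4 had 1 read in microglia (adjusted p 0.000453; exact permutation p 0.1, the smallest possible). Ly6c2 was at least 19392-fold higher (adjusted p 0.00045), Chil3, a secreted lectin of monocytes, at least 4057-fold (1807-fold without KO monocytes 1, adjusted p 5.83e-05), Cd24a at least 3210-fold (adjusted p 7.87e-06) and Atp8b4 at least 1514-fold (adjusted p 0.000145). With 1 or 2 reads in microglia, Slfn4 was at 5738 ± 1506 against 0.591 ± 0.513 (adjusted p 0.000344), Retnlg at 3123 ± 2475 against 0.287 ± 0.498 (adjusted p 4.95e-05), Gpr171 at 1993 ± 604 against 0.287 ± 0.498 (adjusted p 4.41e-05) and the ectoenzyme Cd38 at 2462 ± 1186 against 0.624 ± 1.08 (adjusted p 0.00079). Gpnmb rose by 11.12 (SE 0.97) and Plbd1 by 10.72 (SE 1.11). Among lower genes, Nav3 had a log2 fold of -10.40 (SE 1.31) and Capn3 -8.70 (SE 1.18). Upk1b, Cd79b, Armcx2, Galnt12, Ptprm, Tnfrsf17 and Tmem144 were at 0 in monocytes and at least 1941-fold, 877-fold, 810.3-fold, 783-fold, 764-fold, 750.1-fold and 729-fold lower (adjusted p 0.0105 to 0.0343). The ephrin Efnb2, with 3 reads in monocytes, was at 0.703 ± 0.913 against 892 ± 369.6 (adjusted p 0.013).

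In the homeostatic microglia list 21 of 28 genes fell (27 adjusted over the list alone; median -3.30, adjusted p 2.04e-26; adjusted p = 0.000641 with an estimated correlation), with Adgrg1 at -7.24 (SE 1.80) and the matrix protein Sparc at -5.02 (SE 0.52). In the monocyte list 29 of 32 rose (31 adjusted over the list alone; median 6.44, adjusted p 2.8e-45; adjusted p = 5.83e-06 with an estimated correlation). In the neutrophil list 9 of 16 rose (10 rose and 1 fell adjusted over the list alone; median 6.96, or 8.48 with bounds; adjusted p 2.65e-11; adjusted p = 0.017 with an estimated correlation), with the decoy receptor Il1r2 at 10.15 (SE 1.44) and S100a8 at 9.54 (SE 2.28). In the border-associated macrophage list 4 of 11 rose (4 adjusted over the list alone; median 1.60, adjusted p 2.29e-05; adjusted p = 0.0083 with an estimated correlation), with Ms4a7 at 6.04 (SE 0.42) and the platelet factor Pf4 at 5.05 (SE 0.57). In the MHC class II list 4 of 10 rose (4 adjusted over the list alone; median 1.61, adjusted p 0.000255; adjusted p = 0.0421 with an estimated correlation), with H2-Ab1 at 7.48 (SE 0.64). In the chemokine receptor list 6 of 14 rose and 1 fell (7 rose and 1 fell adjusted over the list alone; median 1.67, adjusted p 1.62e-05; adjusted p = 0.0083 with an estimated correlation), with Ccr2 at 7.15 (SE 0.49) and the formyl peptide receptors Fpr2 and Fpr1 at least 438-fold (287-fold without KO monocytes 1) and 362-fold higher. Cxcr4, whose rise may follow from the sort, is among the called genes here too, and the list was not tested without it.

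In the alternative activation list 10 of 17 rose and 1 fell (10 rose and 1 fell adjusted over the list alone; median 3.60, adjusted p 2.66e-09; adjusted p = 0.00615 with an estimated correlation), with the cytokine Il10 at 9.97 (SE 2.10). In the adhesion list 8 of 20 rose and 2 fell (11 rose and 3 fell adjusted over the list alone; median 3.30, adjusted p 2.35e-05; adjusted p = 0.0385 with an estimated correlation). In the glycolysis and hypoxia list 8 of 21 rose and 1 fell (11 rose and 3 fell adjusted over the list alone; median 0.98, adjusted p 1.86e-05; adjusted p = 0.0142 with an estimated correlation), with Ndrg1 at 7.96 (SE 1.22). In the cell cycle list Cdk1 fell (log2 -6.63, SE 1.56) among 26 genes (2 adjusted over the list alone; median -1.94, adjusted p 0.000753; adjusted p = 0.0153 with an estimated correlation).

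Calls of 7 lists were lost with an estimated correlation. In the progenitor list 3 of 7 genes rose and Cd34 fell (4 rose and 1 fell adjusted over the list alone; median 5.14, adjusted p 0.00558; adjusted p = 0.195 with an estimated correlation), with Elane, Prtn3 and Ctsg at least 802-fold, 449-fold and 360-fold higher (Elane 198-fold and Ctsg 190-fold without KO monocytes 1, adjusted p with all libraries 0.000761, 0.00144 and 0.0159). Among T and NK cell genes 1 of 6 rose (2 adjusted over the list alone; median 1.8, adjusted p 0.0143; adjusted p = 0.116 with an estimated correlation). In the inflammatory list 9 of 20 rose and 4 fell (10 rose and 4 fell adjusted over the list alone; median 1.18, adjusted p 0.000385; adjusted p = 0.23 with an estimated correlation), with Cxcl1 at 7.66 (SE 2.02). In the interferon list 4 of 21 rose (10 adjusted over the list alone; median 1.34, adjusted p 2.66e-09; adjusted p = 0.195 with an estimated correlation), with Irf7 at 2.92 (SE 0.50). In the MHC class I list 1 of 13 rose (4 adjusted over the list alone; median 0.71, adjusted p 0.0026; adjusted p = 0.213 with an estimated correlation). In the disease-associated microglia list 7 of 21 rose and 3 fell (7 rose and 6 fell adjusted over the list alone; median 0.39, adjusted p 0.00949; adjusted p = 0.277 with an estimated correlation), with Apoe at 4.10 (SE 0.41). In the immediate early list 5 of 18 fell and 1 rose (6 fell and 2 rose adjusted over the list alone; median -0.53, adjusted p 0.00558; adjusted p = 0.32 with an estimated correlation), with Egr1 at -3.00 (SE 0.49).

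Camera did not call the other 11 tested lists, with adjusted p from 0.0562 (cholesterol) to 0.962 (neuron). Called members were Ermn, an oligodendrocyte gene at least 462-fold lower in monocytes, Slc1a3 (log2 -6.54, SE 0.85), the vascular receptor Kdr (6.58, SE 0.98) and Cd209a (9.61, SE 1.75). In complement, C3 (7.86, SE 2.07), Cd93 (7.19, SE 0.93) and properdin, Cfp (5.89, SE 1.03), rose and 5 genes fell. Sall3 had a log2 fold of -4.74 (SE 0.65). Adjusted over the list alone, these 11 lists had 0 to 5 genes higher and 0 to 6 lower. Signs differed for complement (median -0.65, mean 1.33, camera down), neuron (median -0.38, mean -0.28, camera up) and sex-linked genes (median -0.34, mean -0.12, camera up).

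Groups did not overlap for 3420 genes, 27.5% against 10% by chance. The count of 849 was 522 with edgeR, 1570 with DESeq2, 1378 with array weights, and 482 to 534 without KO microglia 1 (496), 2 (534) or 3 (482) or KO monocytes 1 (496). The majority of 479 higher against 370 lower genes turned to 379 against 422 with upper quartile scaling and 375 against 460 with CPM scaling. The median log2 fold of all genes, -0.248, moved to -0.439 with upper quartile scaling and to -0.485 with CPM scaling, and the lysosome median of 0.03 then turned to -0.17 and -0.22.

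Across 12432 genes, the monocyte-over-microglia folds of KO and control animals had a Pearson r of 0.573 and a Spearman rho of 0.47. Of the 810 genes called in control animals, 772 had the same sign in KO animals. Both called 298 genes higher and 182 lower, against 16.6 and 11.3 by chance, and 0 genes were called in opposite directions. Gpnmb, Cd24a, Ccr2, H2-Ab1 and Apoe were higher and Capn3 and Slc1a3 lower in both.

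**Figure D3:**
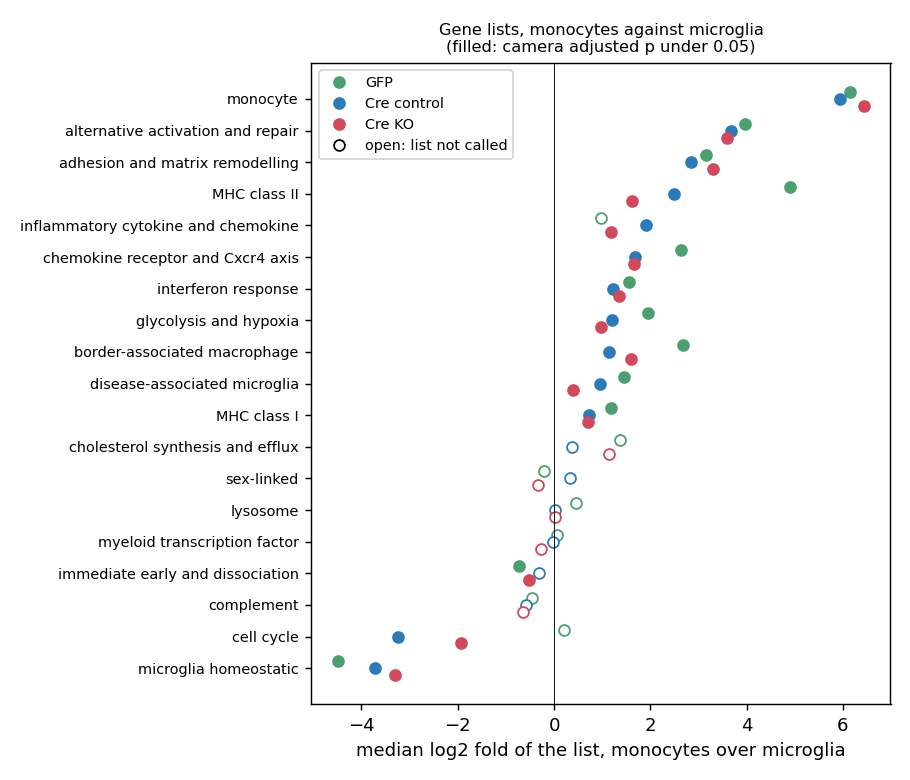
Median log2 fold of monocytes over microglia (x axis) for the 19 gene lists tested in all 3 comparisons (y axis), with GFP mice in green, control mice in blue and KO mice in red; filled points passed camera with the preset correlation. The monocyte list lies at 6.14, 5.93 and 6.44 and the homeostatic microglia list at -4.49, -3.71 and -3.30; cell cycle lies at 0.21 in GFP mice and at -3.24 and -1.94 in the Cre table.

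The fourth question was how monocytes of KO animals differ from those of control animals in the injured brain. KO monocytes carried Elane, the gene of neutrophil elastase, at 862 ± 1129 normalized counts, with 0 in all 3 control libraries. The glucocorticoid-induced TNF receptor gene Tnfrsf18, the uridine phosphorylase Upp1, the signalling adaptor Sh2d1b1 and the lectin receptor Clec4a4 were likewise at 0 in every control library and rose in KO monocytes. By camera with the preset correlation, but not with an estimated one, the hematopoietic progenitor and cell cycle lists were higher in KO monocytes. Cxcr4 itself was at 777 ± 237 in KO against 1227 ± 91.4 in control monocytes, 63.3% of the control mean.

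The log2 fold of Cxcr4 was -0.70 (SE 1.10, adjusted p 0.962 by limma; exact permutation p 0.1, the smallest possible), with each KO library below each control library. It was -1.67 with sex as a covariate and -0.46 without KO monocytes 3. The SE of 1.10 is shared with the microglia groups, whose Cxcr4 means were 2.63 (control) and 0.304 (KO). Near 0 a few reads move log2 values far, so the limma p does not measure the spread among monocytes alone. It does not show that Cxcr4 was unchanged. Limma called 5 of 12432 genes, all higher in KO, and 756 had an unadjusted p under 0.05. Elane was at least 720-fold higher (adjusted p 0.0207, and at least 178-fold without KO monocytes 1), with 2161, 306 and 119 normalized counts in the 3 KO libraries. Sh2d1b1 was at 521 ± 125 and at least 435-fold higher (adjusted p 0.0377). Upp1 was at 348 ± 95.8 and at least 290.1-fold higher (adjusted p 0.0101). Tnfrsf18 was at 165 ± 107 and at least 138-fold higher (adjusted p 0.0207, and at least 87.8-fold without KO monocytes 1), and Clec4a4 at 91.2 ± 13.2 and at least 76.2-fold higher (adjusted p 0.0207). Other granule proteases were not called: Prtn3 was at 483 ± 243 against 4.26 ± 7.38 (log2 7.52, SE 1.25, adjusted p 0.132) and Ctsg at 387 ± 349 against 32.8 ± 56.8 (log2 5.75, SE 1.71, adjusted p 0.539). Mpo, the gene of myeloperoxidase, was not tested and stood at 819, 462 and 0 in KO and at 0 in all control libraries.

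In the progenitor list Elane rose among 7 tested genes (3 adjusted over the list alone), with a median of 2.79 and a camera adjusted p of 0.000389 (adjusted p = 0.294 with an estimated correlation). In the cell cycle list 0 of 26 genes were called (0 adjusted over the list alone), with 17 positive folds, a median of 0.79 and an adjusted p of 0.0157 (adjusted p = 0.184 with an estimated correlation). In it Top2a was at 996 ± 393 against 324 ± 330.4 (adjusted p 0.55) and Cdk1 at 35.4 ± 61.3 against 330.1 ± 314 (adjusted p 0.447). In the neutrophil list, which also holds Elane, that gene alone among 16 rose (1 adjusted over the list alone; median 0.87, adjusted p 0.35). The other 25 tested lists had adjusted p of 0.35 to 0.985, medians from -1.30 to 1.16 and 0 called genes, with 0 or 1 gene per list adjusted over the list alone. They include the monocyte (median 0.07), MHC class II (0.26), interferon (-0.19), inflammatory (-0.06), glycolysis and hypoxia (-0.03), alternative activation (0.02) and chemokine receptor (0.14) lists. Among their members, the formyl peptide receptor Fpr1 was at 389 ± 69.4 against 28.4 ± 49.2 (adjusted p 0.343), the kinase Pdk1 at 694 ± 187 against 86.4 ± 68.2 (adjusted p 0.343), Hk1 at 31.6 ± 16.3 against 369 ± 114 (adjusted p 0.596) and the mannose receptor Mrc1 at 1012 ± 376 against 312 ± 225 (adjusted p 0.712). The cytokine gene Il12b was at 146 ± 40.2 against 0 in all control libraries (adjusted p 0.343). Signs of median, mean and camera differed for dendritic cell, neuron, endothelial, inflammatory, disease-associated microglia and lysosome lists.

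Xist, expressed from the inactive X chromosome of females, was at 2830 and 3348 in KO monocytes 1 and 2, at 118 in KO monocytes 3 and at 104 to 263 in control monocytes. Groups did not overlap for 1096 genes, 8.8% against 10% by chance. Of the 10 splits of these monocyte libraries, 6 had 5 genes or more, the real one included, and the highest other had 16. The 5 calls are thus not told apart from chance. The count of 5 was 0 with edgeR (869 genes at an unadjusted p under 0.05), with sex as a covariate (556), with a filter of 50 (651) or with only these groups in the fit (501), 1 with array weights and 339 with DESeq2 (184 higher and 155 lower). Leaving out 1 library gave 30 genes (control monocytes 1, 27 higher), 26 (control monocytes 3), 13 (KO monocytes 3, 5 higher and 8 lower), 8 (KO monocytes 2, 7 higher), 3 (KO monocytes 1), 2 (control monocytes 2, 1 higher) or 1 (control microglia 3, KO microglia 2 or 3).

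**Figure D4:**
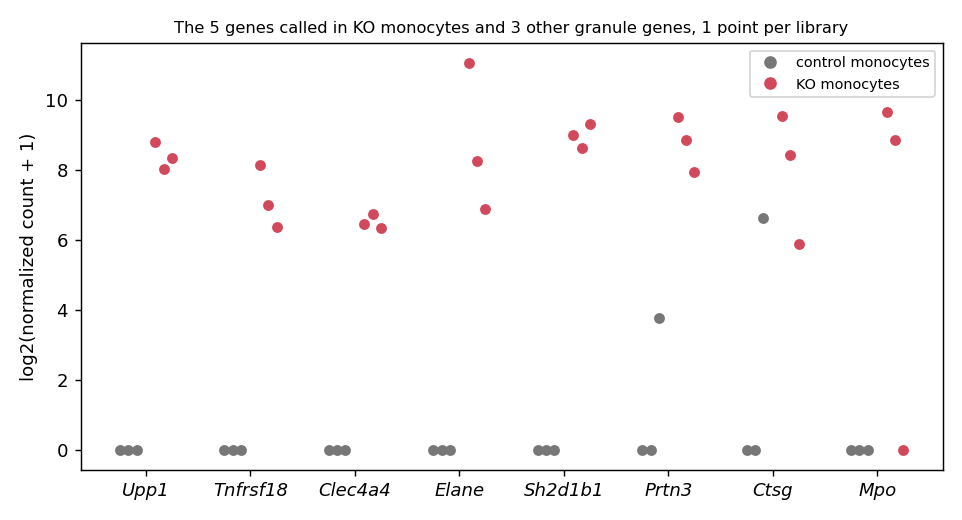
Expression as log2(normalized count + 1) (y axis) of 8 genes (x axis) in the 3 control (grey) and 3 KO (red) monocyte libraries, with 1 point per library. The 5 called genes are at 0 in all control libraries and between 80.8 normalized counts (Clec4a4) and 2161 (Elane) in KO libraries; Prtn3, Ctsg and Mpo were not called.

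The fifth question was how microglia differ between the same genotypes, in which Cxcr4 was near 0 in both genotypes (0.304 ± 0.526 in KO and 2.63 ± 4.55 in control; exact permutation p 1). Ermn, a cytoskeletal gene of myelinating oligodendrocytes, was at 261 ± 124 in KO microglia and at 0 in all 3 control libraries. Aldh1l1, an astrocyte enzyme, and Trip13, a gene of chromosome segregation, were at 191 ± 107 and 84.6 ± 26.0 in control microglia and at 0 in all 3 KO libraries. Tmem177, a mitochondrial membrane gene, was at 155 ± 51.3 in control and at 0.287 ± 0.498, 1 read, in KO microglia.

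Limma called these 4 genes of 12432, 1 higher and 3 lower, and 439 had an unadjusted p under 0.05. Ermn was at least 314-fold higher (adjusted p 0.0253), Aldh1l1 at least 178-fold lower (adjusted p 0.0284) and Trip13 at least 78.7-fold lower (adjusted p 0.0284); the adjusted p of Tmem177 was 0.0284. Cxcr4 had a log2 fold of -0.74 (SE 1.10, adjusted p 1), which was 0.31 without control microglia 2, -1.26 without control microglia 1 or 3, -1.22 with sex as a covariate and -2.60 with DESeq2. Among genes that did not pass, Ccr2 was at 90.9 ± 25.4 in KO against 14.1 ± 8.26 (log2 2.74, SE 0.49, adjusted p 0.243), Syngr4 at 73.8 ± 38.2 against 0.985 ± 1.71 (adjusted p 0.275), Zfp383 at 90.3 ± 119.6 against 0 (adjusted p 0.306) and Myadml2 at 75.8 ± 34.1 against 0 (adjusted p 0.379). The phosphatase Ppp4c had a log2 fold of -1.16 (SE 0.24, adjusted p 0.487), Kdr -4.45 (SE 0.98, adjusted p 0.504) and the hypoxia peptide Adm was at 28.0 ± 13.4 against 0.328 ± 0.568 (adjusted p 0.504). Dus4l was at 0 against 213 ± 118 (adjusted p 0.504).

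Camera called 0 of 28 lists, with adjusted p of 0.181 (interferon, median -0.28, and inflammatory, median 0.31) to 0.981 and medians from -0.70 to 1.14. Of these lists, astrocyte and oligodendrocyte had 1 called gene each, and 0 or 1 gene per direction was called adjusted over the list alone. The homeostatic microglia list had a median of 0.08, MHC class II 0.74, with 10 of 10 folds positive, and disease-associated microglia 0.11. With fry the oligodendrocyte list passed (adjusted p 0.00266, median 0.48). Spp1 was at 24534 ± 5102 in KO against 53376 ± 26343 (adjusted p 1), Cd74 at 2639 ± 928 against 1757 ± 180.4 (adjusted p 1) and the purinergic receptor P2ry13 at 6923 ± 997 against 4672 ± 1143 (adjusted p 1). Signs of median, mean and camera differed for the monocyte, dendritic cell, T and NK cell (median 0.31, or 0.29 with bounds), progenitor, astrocyte, cholesterol and complement lists.

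Groups did not overlap for 1176 genes, 9.5% against 10% by chance, and Xist was at 5726 and 6014 in KO microglia 1 and 2 and at 4453 in control microglia 2, against 87.2 to 191 in the others. Of the 10 splits of these microglia libraries, 2 had 4 genes or more, the real one included, and the highest other had 10. The 4 calls are thus not told apart from chance. Whether the reads of Ermn and Aldh1l1 came from microglia was not tested. The count of 4 was 0 with edgeR (372 genes at an unadjusted p under 0.05), a filter of 50 (343), robust variance (426), sex as a covariate (346) or only these groups in the fit (558), and 109 with DESeq2 (64 higher and 45 lower). Leaving out 1 library gave 8 genes (control microglia 2, 6 higher), 6 (control monocytes 2), 1 (KO microglia 1 or 2) or 0 (control microglia 1 or 3, control monocytes 1 or 3, KO microglia 3, KO monocytes 1, 2 or 3).

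The last question was whether the KO difference differs between monocytes and microglia. For Elane, Upp1 and the other genes above, the genotype-by-population term passed in 0 of 12432 genes by limma, with 590 at an unadjusted p under 0.05, in 0 by edgeR (730) and in 276 by DESeq2. The progenitor list passed camera (median of the term 4.48, adjusted p 0.00928; adjusted p = 0.535 with an estimated correlation; 2 of 7 genes adjusted over the list alone), and the other 27 tested lists did not (adjusted p 0.272 to 0.966). Signs of its median, mean and camera differed for the monocyte, endothelial, chemokine receptor, alternative activation, cholesterol and lysosome lists. Across genes, the KO folds of monocytes and microglia had a Pearson r of 0.011 and a Spearman rho of 0.02.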

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

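The tests of sex, of depth and of the neutrophil lineage for the KO monocyte genes, and those of depth and of mice per sample for the GFP libraries, were chosen only after the results were seen. Among the GFP libraries, 46 measures were tested in 92 groups for 1 library far from the others, and 15 were found. The measures were 42 genes, reads, detected genes, and the shares of Rn45s and of the 10 largest genes. The rule was set to find about 1 in 20 by chance, but this rate does not hold for genes almost without reads. Where all other libraries of a group lacked reads, any read set 1 library apart by construction. This was so for Emp1, Myof, Slfn4 and Cd93 in GFP microglia. The 15 are therefore only listed, and whether they exceed chance was not tested.

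The hematopoietic progenitor list differed between the KO effects of monocytes and microglia (camera adjusted p 0.00928; adjusted p = 0.535 with an estimated correlation), and Elane, one of its genes, is among the 5 genes higher in KO than in control monocytes. A term for sex left their median log2 fold at 8.13, from 8.41, and their folds at 6.46 to 8.39 (at least 5.55 SE). It raised the SE (for Elane from 1.14 to 1.33), so that no gene passed (adjusted p 0.119 to 0.468). The term assumes 1 sex difference for monocytes and microglia alike, so it cannot exclude a sex effect confined to monocytes. By Xist, only KO monocytes 3 matched the control monocytes. That library held all 5 genes, from 80.8 (Clec4a4) to 647 (Sh2d1b1), but it is 1 library. With all libraries thinned to 9.7 M reads the median was 7.29 and all 5 genes passed (adjusted p 0.0105 to 0.0264), which argues against depth. Other cells of the neutrophil lineage stay open: the neutrophil list without Elane and Mpo, which the progenitor list also holds, had a camera p of 0.300 with 12 of 15 folds positive, S100a8 stood at 28290 to 47080 in KO against 10980 to 29640, Ly6g at 3.34 to 258 against 0 to 10.2, but Camp at 0 to 1473 against 11.1 to 2015, Ltf at 0 in 2 of 3 KO libraries and in 0 of 3 controls, and Ngp at 0.668 to 2564 against 0 to 234, and the labels name no gate against such cells. KO monocytes 1 had the highest KO value of S100a8, Ly6g, Camp, Ltf, Ngp and Elane (2161), so these ranges lean on 1 library. It also led in Retnlg (5927 against 1244 and 2197 in KO, 1120 to 1364 in controls) and S100a9 (14320 against 8029 and 7254 in KO, 3979 to 7575 in controls). A direct effect of the genotype on monocytes may also apply and was not separated from such cells. Chance stays open too: 6 of the 10 splits of the monocyte libraries, the real one included, gave 5 genes or more.

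In the GFP table, microglia 3, microglia 4 and monocytes 3 had 5598, 3489 and 3029 detected genes, the last far from the 10422 to 11762 of the other monocytes. With every library thinned to 0.441 M reads outside Rn45s, these 3 had at most 5249 genes and the other 5 at least 9390, which argues against depth. All 3 came from single mice, 3 of 4 such libraries against 0 of 4 pooled ones (Fisher's exact test, two-sided p = 0.143, the smallest that 3 of 8 libraries allow), so this test decides nothing and the number of mice stays open. In the labels, sample numbers of the pooled libraries form a run apart from those of the single-mouse ones. What this numbering reflects is not given, and the number of mice cannot be told apart from it. No biological explanation was tested.

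GFP microglia 2 had 5.55 M reads against 0.617, 0.851 and 1.11 M. GFP monocytes 2 had 14.9 M reads against 0.648, 0.883 and 2.45 M. Emp1 was at 0.430 in GFP microglia 2 and at 0 in the other microglia. Myof was at 0.861 in GFP microglia 2 and at 0 in the others. Slfn4 was at 2.50 in GFP microglia 3 and at 0 in the others. Cd93 was at 4.73 in GFP microglia 2 and at 0 in the others. Ly6c2 was at 3146 in GFP monocytes 3, against 115, 446 and 596. Cd93 was at 15.9 in GFP monocytes 3, against 989, 1124 and 1130. C1qa was at 411 in GFP monocytes 3, against 124, 144 and 153. Jun was at 5340 in GFP microglia 3, against 2004, 2381 and 2463. C1qc was at 1283 in GFP microglia 4, against 2060, 2084 and 2143. Cd44 was at 182 in GFP microglia 4, against 1.25, 9.47 and 15.5. Ms4a7 was at 0 in GFP microglia 4, against 2.15, 2.50 and 2.58. Mki67 was at 127 in GFP microglia 3, against 736, 765 and 798.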

How the results depend on the processing

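DESeq2, the sex covariate and the fit without the 3 GFP libraries under 6000 detected genes were chosen only after the data were seen. The 252 named results are single genes by comparison, without counts, lists or correlations. They include genes that were not called, which count as keeping their side where they stay uncalled. Only called genes can lose a call, so the share kept does not measure how well the calls held. Of the 5831 values of the named results under alternatives, 5111 kept their direction and their side of the threshold, 694 lost the call and 25 gained it. The remaining 1, Cxcr4 in KO against control microglia, turned (0.31 without control microglia 2, adjusted p 1, with -1.26 to 0.31 over the fits without 1 library). The GFP count of 70 genes was 198 with a pseudocount of 10, 38 with no filter, 17 with upper quartile scaling, 106 with CPM scaling, 1923 with array weights, 112 with robust variance, 60 with the animal or pool as a block (52 shared), 187 with DESeq2 (53 shared), 1198 without the libraries of few genes (70 shared), and 33 (without microglia 3) to 129 (without monocytes 3). The control count of 810 was 386 with only the 2 groups in the fit, 478 with edgeR (475 shared), 1614 with DESeq2, and 574 to 806 without 1 library. The KO count of 849 was 1378 with array weights, 522 with edgeR (517 shared), 1570 with DESeq2, and 482 to 1013 without 1 library (482, 496 and 534 without KO microglia 3, 1 and 2; 496 without KO monocytes 1). The 5 KO monocyte genes became 0 with a filter of 50, 0 with only the 2 groups, 0 with edgeR (869 at an unadjusted p under 0.05), 0 with the sex covariate, 1 with array weights, 339 with DESeq2 (2 shared) and 1 to 30 without 1 library (30, 2 and 26 without control monocytes 1, 2 and 3; 3, 8 and 13 without KO monocytes 1, 2 and 3; 1 without control microglia 3 or KO microglia 2 or 3). The 4 KO microglia genes became 0 with a filter of 50, 0 with robust variance, 0 with only the 2 groups, 0 with edgeR (372), 0 with the sex covariate, 109 with DESeq2 (2 shared) and 0 to 8 without 1 library (8 without control microglia 2, 6 without control monocytes 2, 1 without KO microglia 1 or 2, 0 without any other). The genotype-by-population count of 0 was 276 with DESeq2 and 0 to 1 without 1 library (1 without control monocytes 3 or KO monocytes 1). With only the 2 groups, fewer libraries estimate the spread, but the KO count then rose from 849 to 968. The cause of these shifts was not tested.

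Called lists fell with an estimated correlation from 12 to 2 (GFP; 10 with the animal or pool as a block), from 17 to 10 (KO) and from 2 to 0 (KO monocytes), and fry called 3 of the GFP lists and 1 in KO microglia, where camera called 0. Without 1 library, KO monocytes had 1 (without control monocytes 1 or KO monocytes 3) to 4 called lists (without control monocytes 2), and KO microglia 0 to 2 (2 without KO microglia 3; 1 without control microglia 1 or 2 or KO microglia 2). With upper quartile scaling the control dendritic cell (adjusted p 0.0395) and immediate early (0.0403) lists were called too. Directions of called lists held under both scalings; medians of the cell cycle and lysosome lists in GFP mice, 0.21 and 0.45, were -0.51 and -0.11 without the libraries of few genes. The r of GFP with control folds, 0.453, was 0.551 with a filter of 50, 0.622 with array weights, 0.602 without those libraries and 0.396 to 0.477 without 1 library. The r of KO with control folds, 0.573, was 0.505 with edgeR, 0.391 with DESeq2 and 0.518 to 0.575 without 1 library. The r of both KO effects, 0.011, was 0.046 with the sex covariate and -0.005 (without control monocytes 2; 0 without control microglia 1) to 0.023 without 1 library (control microglia 2). The cause was not tested.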

Other observations

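The tests of gene families were chosen only after the data were seen; the splits of the libraries and the test of the genes near Cxcr4 were written before their results, the latter prompted by the call of Tmem177. Genes that share a symbol stem, such as the interferon-induced Ifi genes, formed 280 families of at least 6 tested members in the Cre table. The Ifi family, which shares Ifi204 and Ifi44 with the interferon list, had 15 members: 6 rose in control monocytes over control microglia (median log2 fold 1.85, camera adjusted p 6.44e-08; adjusted p = 0.887 with an estimated correlation) and 7 in KO animals (2.60, adjusted p 1.16e-09; adjusted p = 0.648 with an estimated correlation). Of 7 Slfn genes, which restrain growth and viral replication, 4 rose in control (1.75, adjusted p 8.67e-06; adjusted p = 0.74 with an estimated correlation) and 4 in KO animals (1.52, adjusted p 1.81e-05; adjusted p = 0.64 with an estimated correlation).

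Of 18 Clec genes, C-type lectins that bind sugars of microbes and dying cells, 6 rose in control (median 3.59, adjusted p 0.00114; adjusted p = 0.414 with an estimated correlation) and 8 in KO animals (3.42, adjusted p 2.82e-06; adjusted p = 0.0836 with an estimated correlation). Of 9 annexins, 3 rose and 1 fell in control (1.78, adjusted p 0.0291; adjusted p = 0.887 with an estimated correlation), and 4 rose and 1 fell in KO animals (2.28, adjusted p 0.00175; adjusted p = 0.64 with an estimated correlation). In all, 8 families were called in control and 15 in KO animals, 1 in KO against control monocytes, and 0 of these with an estimated correlation. The medians of the 280 families in control and KO animals had a Spearman correlation of 0.56 across families, above the 0.5 set for like movement in both genotypes.

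Tmem177 lies on the chromosome of Cxcr4 and is gene 87 by distance from it among the tested genes. Its call in KO microglia was lost with edgeR, a filter of 50 or sex as a covariate, each with 0 called genes. The level of Tmem177 in monocytes was not weighed here. A candidate explanation for the low level of Tmem177 in KO microglia is a stretch of other-strain sequence, or of changed expression, kept around the edited Cxcr4 allele. The 100 tested genes nearest to Cxcr4, without Tmem177, were ranked by the mean of their absolute moderated t, summed over KO against control monocytes and microglia. They stood at percentile 93.1 of 1014 windows of the same size, which overlap and are thus not independent. This percentile lies short of the 95 set beforehand and above the 50 set for the opposite, so the explanation stays open.

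The GFP count of 70 genes was reached by 2 of the 35 splits of the 8 libraries, the real one included, so chance is not excluded at 0.05. The other split, with 154 genes, parts microglia 1 and 2 and monocytes 1 and 4 from monocytes 2 and the 3 libraries of few detected genes, a structure of the samples, and parts only 2 of the 4 pairs of libraries from 1 animal or pool. Among the 8 splits that part all 4 pairs, too few for a share under 0.05, the real one alone had 70 genes and the highest other had 1. The split of pooled against single-mouse libraries, which also parts the separate runs of sample numbers, gave 67 genes. The 12 called GFP lists were reached by 2 of 35 splits, the highest other with 12. For 3 against 3 libraries the 10 splits are too few to give a share under 0.05. Control animals had 810 genes in the real split and at most 9 in another (1 of 10 as large), and 14 lists against at most 8 (1 of 10). KO animals had 849 genes against at most 1 (1 of 10), and 17 lists against at most 14 (1 of 10). KO against control monocytes had 5 genes against at most 16 (6 of 10 as large) and 2 lists against at most 4 (5 of 10). KO against control microglia had 4 genes against at most 10 (2 of 10) and 0 lists against at most 3 (10 of 10). The genotype-by-population term had 0 genes, and 100 of 100 drawn splits had as many, with at most 3. Where the real count is 0, every split has as many by construction, so these counts say nothing about chance.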
